A study of Homo sapiens with 18 samples.

How the data were processed

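Gene expression was measured by RNA sequencing in 3 human pancreatic ductal adenocarcinoma cell lines, PANC1, COLO357 and SUIT2, after transfection with small interfering RNAs (siRNAs) against KMT2C or KMT2D, which encode histone H3 lysine methyltransferases that act at enhancers. Each line gave 6 libraries: 1 with a control siRNA, 2 with KMT2D siRNAs (siRNA1 and siRNA2) and 3 with KMT2C siRNAs (siRNA1, siRNA2 and siRNA3), so that 18 libraries were compared. Per the labels' protocols, cells were transfected for 48 h, ribosomal RNA was depleted with Ribo-Zero Gold, libraries were made with the TruSeq stranded total RNA kit, and 100 nt paired ends were read after the samples had been randomised into 7 pools on 7 lanes. Which library was in which pool is not given in the sources used here, so no pool could be entered as a batch.

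Per the submitters' processing notes, the authors used FastQC, TopHat2, HTSeq and edgeR with the hg19 build, with no versions given. The deposited values are raw counts of read pairs per Ensembl gene identifier, 1 table per library, without normalization. The annotation release, the HTSeq overlap mode and its strand setting are not given in the sources used here, so genes that overlap, antisense partners and copies with near-identical sequence may share reads. Each table held 63677 gene identifiers and closed with 5 entries that name no gene (no annotated feature, ambiguous, low alignment quality, not aligned and not uniquely aligned). These entries were kept out of library sizes and tests and made up 32.98% to 53.39% of the read pairs listed, with 0 in the low-quality and not-aligned classes. The share in no annotated feature was 12.8% ± 4.72 (SD, n = 3) with control siRNA, 11.1% ± 1.64 (n = 6) with KMT2D siRNA and 17.2% ± 7.17 (n = 9) with KMT2C siRNA. Symbols and biotypes were taken by identifier from GENCODE v29, an annotation of GRCh38 and so not of the authors' build. They were found for 52181 identifiers (81.9%) and 52526 identifiers, and no coordinates are printed.

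The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization factors (0.946 to 1.06), robust dispersion estimates and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The edgeR filter by expression (minimum count 10, minimum total count 15, groups of cell line by target) kept 21028 genes. All 18 libraries entered one fit with cell line as an additive term, because each line had 1 control library. The contrasts were KMT2D siRNA against control siRNA, KMT2C siRNA against control siRNA, and KMT2C siRNA against KMT2D siRNA. The common biological coefficient of variation was 0.239 on 13 residual degrees of freedom, with a median of 9.16 prior degrees of freedom. A fit with a level for each siRNA (coefficient of variation 0.183, 10 residual degrees of freedom) tested each of the 5 siRNAs against control and counted the genes called in the same direction by every siRNA of a target. A fit with 9 groups of cell line by target (9 residual degrees of freedom) tested each target within a line and the difference of its effect between lines. There the lone control library of a line was assumed to vary like the other groups. Library levels are CPM (counts scaled to library size), and library log2 fold changes are against the control library of the same line with a prior count of 2. Standard errors (SE) of edgeR values were derived from the test, as the size of the log2 fold change over the square root of F.

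Libraries of one group differed by more than sampling noise (chi-square per gene between 30.8 and 166 for the pairs), so none was counted as a copy of another. Nothing in the labels says that libraries came from separate cultures, so the p-values measure the spread between these libraries, which mixes the siRNAs and may be partly technical.

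Before the data were examined, the tests, the alternatives, 24 gene lists and a rule for named genes were fixed. KMT2C and KMT2D are given first in every library. For each target against control, the 10 largest rises and 10 largest falls were named among genes with an adjusted p under 0.05, a mean of at least 2 CPM, an official symbol and a change in the same direction in every library of the target, or as many as passed. For KMT2C against KMT2D siRNA, 5 genes in each direction were named whose target means differed in the same direction in all 3 lines, and for the difference between lines, the 5 with the smallest p per target. For described lists, up to 4 members with the smallest p and members whose call differed between targets were named. The lists covered KMT2 complex partners, cell cycle, p53, interferon, NF-kB, mesenchymal, epithelial, classical and basal-like pancreatic tumour, glycolysis, lipid synthesis, unfolded protein, ribosome biogenesis, WNT, YAP, HOX, MAPK and housekeeping genes, structural and mitochondrially encoded RNAs, and markers of fibroblasts, leukocytes and endothelial cells. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes and again with an estimated one. The mitochondrially encoded and endothelial lists had too few measured members, so 22 lists were tested in each comparison. Counts of called members are given over all genes tested and adjusted over the list alone.

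Similarity between siRNAs was the Pearson correlation across genes of library log2 fold changes between libraries of different cell lines, with an exact permutation of siRNA names within lines. Such libraries share no control library. The controls of all lines carry the same siRNA label, however, so effects of the control siRNA could enter every pair. Comparisons that share the 3 control libraries were set beside 20 simulations of unchanged groups. All 18 libraries, controls included, were drawn there without any siRNA effect. Because an siRNA can lower transcripts whose 3′ untranslated region (UTR) pairs with its seed, and the siRNA sequences were not used here, 16167 heptamers were searched in the longest annotated 3′ UTR of 10379 genes (mean of at least 5 CPM, at least 50 nt of 3′ UTR, heptamer in at least 50 genes). Each library was set against the mean of the other 5 libraries of its line on the log2(CPM + 1) scale, with 3′ UTR length, base composition and expression as covariates and residuals limited to 2. The heptamer most tied to lower levels in 2 lines was ranked among all heptamers in the third line. A gene is said to carry the heptamer of a KMT2C or KMT2D siRNA where it held the 1 ranked first over the 3 lines. A gene without it may still hold another site of that siRNA. For the control siRNA, the 5 heptamers most tied to lower levels were found again without the genes raised by all 5 other siRNAs, a step chosen after the data had been seen, and a gene is said to carry a control heptamer where it held any of them. Lists of genes were compared with 10000 random lists matched on 3′ UTR length. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

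On counts simulated for the 21028 genes, the KMT2D comparison recovered 7.46%, 37.3% and 84.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 3.37% of calls false, so that changes under 2-fold were mostly below its reach. DESeq2 recovered 14.9%, 43.3% and 84.8% there with 14.4% of calls false. The KMT2C comparison recovered 43.3% of 2-fold and 80.3% of 4-fold changes, the KMT2C against KMT2D comparison 59.7% and 86.4%, the KMT2D comparison within COLO357 40.9% of 4-fold changes, and the test of a difference between lines 18.2% of them. Apart from the planted changes, each library was drawn independently, with no effect shared by the libraries of an siRNA. The recovered and false shares may therefore not hold for the real counts, where such effects are present. In 10379 genes a planted heptamer shift of -0.2 on the log2 scale was found in 20 of 20 draws, and 0 of 20 draws without one gave a heptamer within the lowest 0.001.

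Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, other filters on low counts, limma-voom with and without each siRNA as a random block, and fits without each library, siRNA or cell line in turn. Depth was 14205640 to 32115894 gene counts per library, so that counting error was small beside the spread between libraries for all but low genes. Genes at or near 0 CPM in a line carry no information on it.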

Results

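The transcriptomes of 3 pancreatic ductal adenocarcinoma cell lines were compared after siRNA against KMT2C or KMT2D, to ask how loss of either histone methyltransferase changes gene expression. PANC1, COLO357 and SUIT2 cells each gave 6 libraries of ribosome-depleted total RNA: 1 with a control siRNA, 2 with different KMT2D siRNAs and 3 with different KMT2C siRNAs. Depth was 17974599 to 32115894 gene counts in PANC1, 15822531 to 23950329 in COLO357 and 14205640 to 25632462 in SUIT2. The small nuclear RNA 7SK had the highest count in 17 of the 18 libraries (1.38% to 2.03% of gene counts). In the remaining library, COLO357 with KMT2C siRNA3, the identifier ENSG00000226958, to which no name was matched, took 2.49%. Read pairs in no annotated feature made up more than 20% in 3 libraries, COLO357 KMT2C siRNA3 (30.36%), SUIT2 KMT2C siRNA2 (24.99%) and SUIT2 KMT2C siRNA3 (22.2%).

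KMT2C mRNA (ENSG00000055609) lay at 68.6% ± 21.2 (SD, n = 9) of the same line's control with KMT2C siRNA and KMT2D mRNA (ENSG00000167548) at 59% ± 20.7 (n = 6) with KMT2D siRNA. In PANC1, KMT2C was at 62.8%, 116% and 72.3% of control with KMT2C siRNA1, siRNA2 and siRNA3, from 51 CPM in the control. In COLO357 it was at 48.5%, 62.6% and 82.1% of 89.1 CPM, and in SUIT2 at 43.2%, 65.7% and 64.1% of 143 CPM. KMT2D was at 79.9% and 84.7% of control with KMT2D siRNA1 and siRNA2 in PANC1 (27.4 CPM in the control), at 43.5% and 45.5% in COLO357 (32.2 CPM) and at 34.8% and 65.8% in SUIT2 (67.3 CPM). The library labelled PANC1 KMT2C siRNA2 thus did not show less KMT2C mRNA than its control and is named by its label below. It carried the most KMT2D mRNA of all libraries relative to control, 372%. The mRNA that was not targeted lay above control in most libraries: KMT2D averaged 168% ± 82.8 (n = 9, 99.1% to 372%) with KMT2C siRNA, and KMT2C averaged 142% ± 68.9 (n = 6, 92.7% to 274%) with KMT2D siRNA. The 3′ UTR of KMT2D held a heptamer found for the control siRNA. Whether that siRNA itself affects the level of KMT2D against control was not tested. None of these 4 changes passed the adjusted threshold of edgeR's quasi-likelihood test. KMT2C fell by 0.58 on the log2 scale (SE 0.23, adjusted p = 0.437) with its own siRNAs and KMT2D fell by 0.83 (SE 0.29, adjusted p = 0.211) with its own. KMT2D with KMT2C siRNA was at 0.69 (SE 0.29, adjusted p = 0.471) and KMT2C with KMT2D siRNA at 0.43 (SE 0.257, adjusted p = 0.53).

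**Figure D1:**
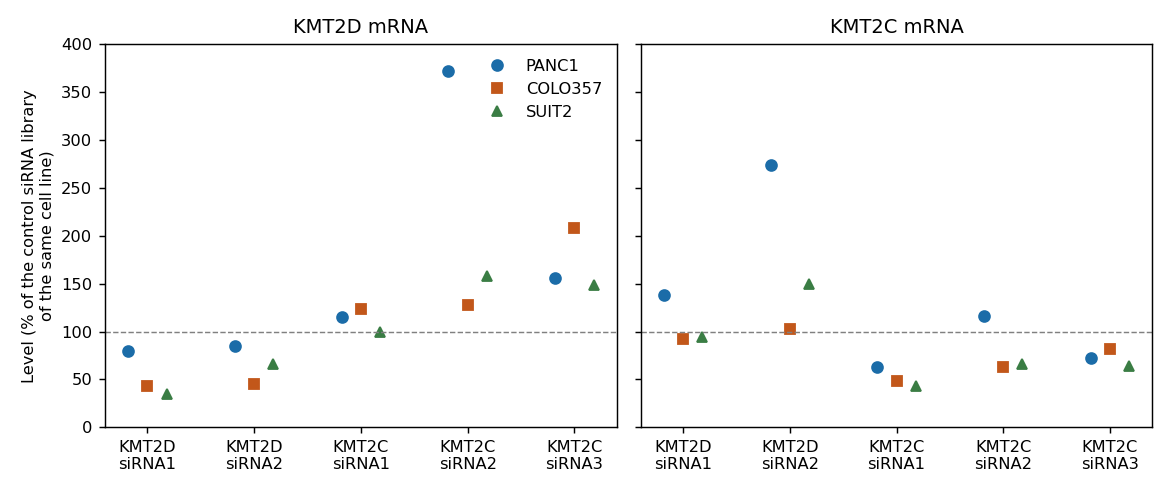
KMT2D mRNA (left) and KMT2C mRNA (right) in each siRNA library as a percentage of the control siRNA library of the same cell line, by siRNA on the x axis, with a marker for each cell line and a dashed line at 100%. KMT2D lies at 34.8% to 84.7% with its own siRNAs, and KMT2C lies below control with its own siRNAs in all libraries but the one labelled PANC1 KMT2C siRNA2 (116%).

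KMT2D siRNA raised CLDN1 (ENSG00000163347), which encodes a tight junction claudin, 4.83-fold and MET (ENSG00000105976), the hepatocyte growth factor receptor, 3.37-fold. It lowered PIK3CB (ENSG00000051382), the catalytic p110-beta subunit of phosphoinositide 3-kinase, 3.15-fold and the keratin KRT80 (ENSG00000167767) 3.09-fold, each in 6 of 6 libraries, as the naming rule required. CLDN1 levels went from 9.72 CPM in the PANC1 control to 36.7 and 85.3 CPM, and PIK3CB from 129 CPM in the SUIT2 control to 30.5 and 34.8 CPM. In all, 253 genes were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, 147 higher and 106 lower, of which 135 and 84 passed the naming rule. Log2 fold changes were 2.27 for CLDN1 (SE 0.506, adjusted p = 0.0371), 1.75 for MET (SE 0.297, adjusted p = 0.00388), -1.66 for PIK3CB (SE 0.168, adjusted p = 2.92e-05) and -1.63 for KRT80 (SE 0.252, adjusted p = 0.00174). The other raised genes with the largest changes were the MAX-binding repressor MXD4 (2.0), the metalloprotease family member ADAM32 (1.94) and the methionine sulfoxide reductase MSRB3 (1.92). They were followed by the intracellular fibroblast growth factor family member FGF14 (1.91), gliomedin GLDN (1.89), the mitochondrial cardiolipin-synthesis phosphatase PTPMT1 (1.84), the ubiquitin ligase subunit WSB1 (1.77, adjusted p = 0.000129) and MINAR1 (1.74). The other lowered genes were SERTAD4 (-1.77), the receptors GPR63 (-1.65) and PTAFR (-1.64), TMPPE (-1.46), gamma-synuclein SNCG (-1.45), the carnosine N-methyltransferase CARNMT1 (-1.44) and the processed pseudogenes HNRNPA1P33 (-1.51) and LYPLA1P3 (-1.41). The pseudogenes are uncertain because they can share reads with their parent genes, as are FGF14 and PTPMT1, whose exons overlap another gene. Both KMT2D siRNAs changed 18 of these 20 genes in the same direction when tested alone, the exceptions being FGF14 (adjusted p = 0.0631 with siRNA1) and SNCG (adjusted p = 0.0524 with siRNA1). The 3′ UTRs of PIK3CB and SERTAD4 held the heptamers found for both KMT2D siRNAs and that of CARNMT1 the one found for siRNA2, as did those of MXD4 and WSB1, which rose. CLDN1, MSRB3, WSB1, MET and KRT80 held one of those found for the control siRNA. Of 122 searched genes raised with KMT2D siRNA, 71 held one (58.2% against 12.4% of other genes), although only the genes raised by all 5 siRNAs had been left out when these heptamers were found. Without KMT2D siRNA2 the calls of CLDN1 (adjusted p = 0.114), FGF14 (0.108), SERTAD4 (0.0783), GPR63 (0.0775), TMPPE (0.0775) and SNCG (0.0653) ended, and without siRNA1 those of GPR63 (0.0596) and SNCG (0.0905). The count rested on the control libraries, being 80, 138 and 36 without the PANC1, COLO357 or SUIT2 control, and of the 20 genes only WSB1 and PIK3CB were still called without the SUIT2 control. It was 77 in limma-voom with each siRNA as a random block, where CLDN1, FGF14, GLDN, SERTAD4, GPR63, PTAFR, KRT80, TMPPE, SNCG and LYPLA1P3 were no longer called.

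**Figure D2:**
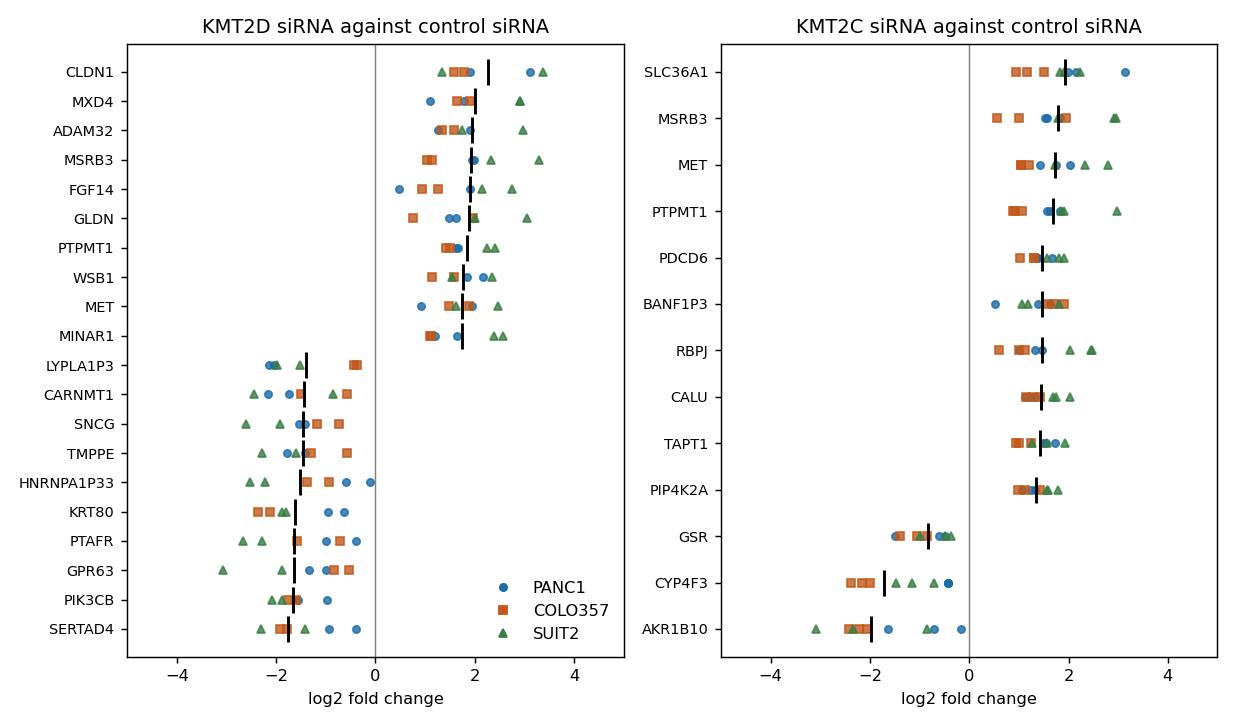
Log2 fold change of each named gene with KMT2D siRNA (left) and KMT2C siRNA (right) against control siRNA, with a point for each library against the control of its own cell line, coloured by line, and a black bar for the fitted value. Every point lies on the same side of 0 as its bar, as the naming rule required. Fitted values run from CLDN1 (2.27) to SERTAD4 (-1.77) with KMT2D siRNA and from SLC36A1 (1.92) to AKR1B10 (-1.98) with KMT2C siRNA.

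With KMT2D siRNA few members of the fixed lists passed the test, and the calls of whole lists held only with the preset correlation. Of 24 genes of the G1/S transition and DNA replication, 3 fell over all genes tested and 7 when adjusted over the list alone, with a median log2 fold change of -0.38 (camera, adjusted p = 1.16e-09; adjusted p = 0.296 with an estimated correlation). The 3 were the DNA polymerase alpha subunit POLA1 (-1.06, adjusted p = 0.0118), the replication checkpoint adaptor CLSPN (-0.80, adjusted p = 0.015) and the helicase cofactor CDC45 (-0.81, adjusted p = 0.015), and the list alone added RRM2 (-0.58), CDC6 (-0.74), MCM5 (-0.55) and MCM3 (-0.38). Of 24 genes of G2/M and mitosis, 1 fell, the topoisomerase TOP2A (-1.03, adjusted p = 0.03), or 2 adjusted over the list alone with the kinase AURKB (-0.71), and the list was lower (adjusted p = 9.57e-06; adjusted p = 0.404 with an estimated correlation). POLA1 carried the heptamer found for KMT2D siRNA1. CLSPN, CDC45, TOP2A and AURKB did not carry the 1 heptamer counted for either KMT2D siRNA. PDIA4 and PTPN14, named next, rose with all 5 siRNAs and carried a control heptamer. Of 22 genes of the unfolded protein and amino acid stress response, 1 rose, the endoplasmic reticulum disulfide isomerase PDIA4 (1.15, adjusted p = 0.00417), or 2 adjusted over the list alone with CHAC1 (1.20). The list was higher (adjusted p = 0.000299; adjusted p = 0.404 with an estimated correlation). Of 25 genes of cholesterol and fatty acid synthesis 0 were called over all genes and 1, FASN (-0.85), fell adjusted over the list alone, with the list lower (adjusted p = 0.0058; adjusted p = 0.781 with an estimated correlation). Of 22 mesenchymal genes 0 were called over all genes and 1, tenascin TNC (0.89), rose adjusted over the list alone, with the list higher (adjusted p = 0.0232; adjusted p = 0.404 with an estimated correlation). Without KMT2D siRNA2 the calls of the unfolded protein list (adjusted p = 0.183) and the mesenchymal list (adjusted p = 0.491) ended and the lipid list changed direction (adjusted p = 0.649), while the interferon list (higher, adjusted p = 0.0296) and the ribosome list (lower, 0.0108) were called. Without siRNA1 the YAP and TGF-beta list (0.00405) and the MAPK list (0.00491) were called as higher. Single members rose or fell in lists that were not called. The CDK inhibitor CDKN1B (0.89, adjusted p = 0.0339) rose among 22 CDK inhibitors and p53 targets (list adjusted p = 0.12) and the phosphatase PTPN14 (1.47, adjusted p = 0.00054) among 23 YAP and TGF-beta targets (0.11). The transcription factor ETV4 (-1.20, adjusted p = 0.0158) fell among 21 MAPK feedback and immediate early genes (0.138). Adjusted over the list alone, SESN1 (0.73), ID2 (1.10), SPRED1 (0.56), HMGA2 (1.21) and SPRED2 (0.60) also rose in these 3 lists. CLDN1 was the one called member of 22 epithelial genes (list adjusted p = 0.432). No member was called, over all genes or adjusted over the list alone, among the interferon response (27 genes, list adjusted p = 0.0576), NF-kB and inflammatory cytokines (0.962), classical (0.983) and basal-like (0.627) pancreatic tumour genes, and glycolysis and hypoxia (0.243). The same held for ribosome biogenesis and MYC targets (0.146), WNT targets (0.891), HOX genes (0.432), housekeeping genes (0.929), structural RNAs (0.657), fibroblast (0.432) and leukocyte markers (0.657) and KMT2 complex partners (0.999). For the partners and the basal-like genes the test pointed down while the median and mean lay above 0.

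KMT2C siRNA raised SLC36A1 (ENSG00000123643), a lysosomal proton-coupled amino acid transporter, 3.79-fold, MET 3.3-fold, RBPJ (ENSG00000168214), the DNA-binding mediator of Notch signalling, 2.75-fold and CALU (ENSG00000128595), a calcium-binding protein of the endoplasmic reticulum, 2.71-fold. It lowered the aldo-keto reductase AKR1B10 3.95-fold, the leukotriene hydroxylase CYP4F3 (ENSG00000186529) 3.29-fold and the glutathione reductase GSR (ENSG00000104687) 1.78-fold. As the naming rule required, all 7 moved in the same direction in 9 of 9 libraries, including the library labelled PANC1 KMT2C siRNA2. CALU went from 118 CPM in the SUIT2 control to between 381 and 484 CPM, and AKR1B10 from 346 CPM in the COLO357 control to between 64.1 and 83.4 CPM. AKR1B10 and CYP4F3 were near 0 in the PANC1 control (0.198 and 0.0329 CPM), so that PANC1 adds little to their falls. In all, edgeR called 59 genes, 56 higher and 3 lower, and 55 and 3 passed the naming rule. Log2 fold changes were 1.92 for SLC36A1 (SE 0.341, adjusted p = 0.00974), 1.72 for MET (SE 0.288, adjusted p = 0.00658), 1.46 for RBPJ (SE 0.209, adjusted p = 0.00155) and 1.44 for CALU (SE 0.159, adjusted p = 0.000147). They were -1.98 for AKR1B10 (SE 0.406, adjusted p = 0.0455), -1.72 for CYP4F3 (SE 0.271, adjusted p = 0.00302) and -0.83 for GSR (SE 0.171, adjusted p = 0.0317). The other raised genes were MSRB3 (1.78), PTPMT1 (1.69), the calcium-binding protein PDCD6 (1.47), the pseudogene BANF1P3 (1.47), which can share reads with BANF1, TAPT1 (1.43) and the phosphatidylinositol phosphate kinase PIP4K2A (1.36). The 3′ UTRs of SLC36A1, MSRB3, MET, RBPJ, TAPT1 and PIP4K2A held a heptamer found for the control siRNA, and those of PDCD6, CALU, AKR1B10, CYP4F3 and GSR did not. Of 51 searched genes raised with KMT2C siRNA, 37 held one (72.5% against 12.6% of other genes), with the same limit as for KMT2D. MSRB3, which rose, also held the heptamer found for KMT2C siRNA1, and MET, which rose as well, the heptamer found for KMT2C siRNA2. KMT2C libraries held more read pairs in no annotated feature (17.2% ± 7.17) than controls (12.8% ± 4.72). The count was 46 without the library labelled PANC1 KMT2C siRNA2 but 13 without the PANC1 control and 7 without the SUIT2 control, where SLC36A1, MSRB3, MET, PTPMT1, PDCD6, BANF1P3, TAPT1, AKR1B10 and GSR were no longer called. The calls of MSRB3, BANF1P3 and AKR1B10 ended without KMT2C siRNA1, those of MSRB3 and AKR1B10 without siRNA2 and that of GSR without siRNA3 (adjusted p from 0.0514 to 0.182). Most single libraries left out ended the call of AKR1B10, and the siRNA block of limma-voom (26 genes) ended those of SLC36A1, PTPMT1, BANF1P3 and GSR.

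Among the fixed lists, PDIA4 (1.10, adjusted p = 0.00808) and PTPN14 (1.22, adjusted p = 0.0025) were the 2 members called with KMT2C siRNA over all genes. Both carried a control heptamer and rose with all 5 siRNAs. POLA1, CLSPN, CDC45, TOP2A, CDKN1B, CLDN1 and ETV4, which were called with KMT2D siRNA, were not called. Adjusted over the list alone, SPRY2 (0.66) among the MAPK genes, CDKN1A (0.89) among the p53 targets and TBP (0.50) among the housekeeping genes rose as well. Of 10 lists called by camera, 5 were higher: MAPK feedback and immediate early genes (adjusted p = 1.84e-05), the interferon response (adjusted p = 0.00065), KMT2 complex partners (adjusted p = 0.0112), WNT targets (adjusted p = 0.0202) and the unfolded protein response (adjusted p = 0.0319). With an estimated correlation these had adjusted p = 0.467 for the MAPK and WNT lists and adjusted p = 0.483 for the other 3. The interferon list had a positive value in 25 of 27 genes and a median of 0.49, with RIGI at 0.72 and IFI44 at 0.81, and the WNT list in 16 of 19 genes. Lower lists were ribosome biogenesis and MYC targets (adjusted p = 0.000215), cholesterol and fatty acid synthesis (0.00304), G1/S (0.0202), G2/M (0.0206) and classical pancreatic tumour genes (0.0397), each with adjusted p = 0.483 with an estimated correlation. The nucleolar proteins NPM1 (-0.51) and NOP56 (-0.54) had the smallest p of the ribosome list, and AGR2 (-0.73) that of the classical list. Without KMT2C siRNA2 the calls of the ribosome, lipid and classical (each adjusted p = 0.0733), G1/S (0.207), G2/M (0.251) and unfolded protein lists (0.114) ended. Without KMT2C siRNA1 those of the classical (0.112) and unfolded protein lists (0.104) ended, and without siRNA3 the mesenchymal list (0.0429) was called as higher and the epithelial (0.0193) and basal-like lists (0.0217) as lower. The other lists had adjusted p of 0.0717 for basal-like genes, 0.0915 for epithelial genes, 0.123 for leukocyte markers, 0.186 for housekeeping genes, and 0.238 for mesenchymal genes. They had 0.32 for YAP and TGF-beta targets, 0.389 for glycolysis, 0.396 for p53 targets, structural RNAs and fibroblast markers, and 0.976 for HOX genes and for NF-kB genes. For NF-kB genes the test pointed down while the median and mean lay above 0, and for glycolysis the median lay above 0 while the mean and the test did not.

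KMT2C siRNA was next contrasted with KMT2D siRNA, with the control libraries entering only through the filter and the shared estimate of the spread (967, 916 and 946 genes without the PANC1, COLO357 or SUIT2 control, against 1087). KMT2D itself was 2.87-fold higher with KMT2C siRNA than with KMT2D siRNA, PIK3CB 2.78-fold higher and MDC1 (ENSG00000137337), a mediator of the DNA damage checkpoint, 2.83-fold higher. SCEL (ENSG00000136155), a cornified envelope precursor protein, was 4.42-fold lower and ALDH1A1 (ENSG00000165092), a retinaldehyde dehydrogenase, 2.65-fold lower. MDC1 lay at 33.3 and 16.7 CPM in PANC1, 23.1 and 16.4 CPM in COLO357 and 23.1 and 16 CPM in SUIT2 with KMT2D siRNA1 and siRNA2, against 44.8, 48.4 and 61.2 CPM in the controls. ALDH1A1 was expressed in COLO357 alone (at most 0.352 CPM elsewhere), where it went from 190 CPM in the control to between 70.2 and 106 CPM with KMT2C siRNA, beside 174 and 247 CPM with KMT2D siRNA. The test called 1087 genes, 515 higher and 572 lower with KMT2C siRNA, of which 407 and 462 kept the direction in all 3 lines. Log2 differences were 1.52 for KMT2D (SE 0.233, adjusted p = 0.00195), 1.5 for MDC1 (SE 0.201, adjusted p = 0.000675), and 1.73 for the growth factor IGF2 (ENSG00000167244; SE 0.344, adjusted p = 0.00942). They were 1.48 for PIK3CB (adjusted p = 5.62e-06) and 1.48 for the sperm calcium channel CATSPER1 (adjusted p = 0.0205). They were -2.14 for SCEL (SE 0.4, adjusted p = 0.00741), -1.41 for ALDH1A1 (SE 0.285, adjusted p = 0.00886), -1.77 for the sulfotransferase CHST4 (adjusted p = 0.023), -1.59 for the protocadherin PCDH18 (adjusted p = 0.0288) and -1.48 for ceruloplasmin CP (adjusted p = 0.00741). IGF2 rested on SUIT2 (187, 297 and 542 CPM against 73.8 and 65.5 CPM), with at most 0.66 CPM in COLO357, SCEL lay at 0.0908 CPM or less in PANC1, and IGF2 and CP overlap other genes, so that reads may be shared. PCDH18, mainly seen in PANC1, was at 8.87 CPM in the library labelled PANC1 KMT2C siRNA2, above its control (2.57 CPM). MDC1, IGF2 and ALDH1A1 carried none of the heptamers counted, which were 1 for each KMT2C or KMT2D siRNA and those of the control siRNA. PIK3CB carried those of both KMT2D siRNAs, SCEL that of KMT2D siRNA2 and KMT2D a control heptamer. The libraries differed by 6.05 percentage points in the share of read pairs in no annotated feature (17.2% ± 7.17 with KMT2C siRNA, 11.1% ± 1.64 with KMT2D siRNA; exact permutation p = 0.04, 2-sided, over 1000 relabelings within lines). The count was 153 with that share as a covariate and 342 without the 3 libraries above 20%. It was 369 without KMT2C siRNA3, but 1839 and 1651 without KMT2D siRNA1 or siRNA2. It was 672 without COLO357 KMT2D siRNA2, 708 without SUIT2 KMT2D siRNA1, 288 with the siRNA block and 986 without the library labelled PANC1 KMT2C siRNA2. CATSPER1 and CHST4 were not called without SUIT2 KMT2D siRNA1, CATSPER1 without SUIT2 KMT2C siRNA1, CHST4 without SUIT2 KMT2C siRNA3, and PCDH18 without PANC1 KMT2D siRNA2 or PANC1 KMT2C siRNA3. With a whole siRNA left out, at least 1 of CATSPER1, CHST4 and PCDH18 lost its call for each of the 5 siRNAs, as did IGF2 without KMT2D siRNA2 (adjusted p from 0.0508 to 0.129).

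Between the targets, too, the calls of whole lists held only with the preset correlation. Of 24 G1/S and replication genes 6 were higher, POLA1 (1.04), CLSPN (0.77), CDC45 (0.64), E2F2 (0.71), MCM5 (0.48) and E2F1 (0.57), or 7 adjusted over the list alone (camera, adjusted p = 9.88e-05; adjusted p = 0.614 with an estimated correlation). Of 24 G2/M genes 3 were higher, TOP2A (0.85), the proliferation marker MKI67 (0.74) and AURKB (0.50), or 5 adjusted over the list alone (adjusted p = 0.0357; adjusted p = 0.71 with an estimated correlation). Of 16 KMT2 complex partners and paralogs 2 were higher, HCFC1 (0.73) and the methyltransferase SETD1A (0.69), or 3 adjusted over the list alone with KMT2A (0.43; list adjusted p = 0.0357; adjusted p = 0.614 with an estimated correlation). In lists that were not called (adjusted p from 0.0974 to 0.902), AGR2 (-1.29), TSPAN8 (-1.33), ID2 (-1.14) and ID1 (-0.72) were lower with KMT2C siRNA, and ETV4 (1.03), TCF7 (0.99), FASN (0.69), SREBF2 (0.60) and CDKN1A (0.82) were higher. Adjusted over the list alone, 5 mesenchymal genes, among them TNC, MMP2 and FBN1, were lower. For NF-kB genes the mean, and for lipid genes the median and mean, differed in sign from the test. Without KMT2D siRNA2 (adjusted p = 0.0884) or KMT2C siRNA1 (0.274) the G2/M list was not called, nor was the partner list without KMT2D siRNA1 (0.218), KMT2C siRNA2 (0.065) or KMT2C siRNA3 (0.0935), and the lipid list was called as lower without KMT2D siRNA2 (0.00146) and as higher without siRNA1 (6.14e-05). Other lists gained a call: the mesenchymal (0.0147), unfolded protein (0.00151), ribosome (0.0147) and YAP lists (0.0176) as lower without KMT2D siRNA1, and the ribosome list without KMT2C siRNA3 (0.00927). The MAPK list was called as higher without KMT2D siRNA2 (0.00315) or KMT2C siRNA2 (0.000997).

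To separate changes shared by the siRNAs of a target from those of a single siRNA, each siRNA was tested against control. PTPMT1 (mean log2 fold change of 1.75), MET (1.71), SLC36A1 (1.66), WSB1 (1.47), RBPJ (1.46), PDCD6 (1.44), CALU (1.38) and 30 further genes rose with all 5 siRNAs, and 0 fell with all 5. Independent lists of these sizes would share 1.37e-05 genes. Among the 37 were the nuclear lamina protein gene BANF1 (1.21), its pseudogene BANF1P3 (1.5), H3-3A (0.91) and its pseudogene H3P6 (1.24), which share sequence and are uncertain, and the phosphatases PTPN14 (1.31) and PTPN1 (1.09). Both KMT2D siRNAs raised 172 genes and lowered 85 (15.4 and 22.6 for independent lists). KMT2D siRNA2 and KMT2C siRNA2, which differ in target, shared a larger number, 216 raised and 118 lowered genes (22.4 and 32.6). KMT2C siRNA2 called more genes alone (1222) than KMT2D siRNA1 (845). Relative to independent lists the 2 KMT2D siRNAs shared slightly more. Both pairs lay above independent lists, so sharing above them does not by itself mark an effect of the target. Simulated unchanged groups with shared controls gave 0 genes shared by both KMT2D siRNAs, by all 3 KMT2C siRNAs or by all 5 in each of 20 simulations. No siRNA effect was drawn in them, so a count of 0 says little beside real changes. Part of the sharing may come from the 3 controls. Of the 257 genes shared by both KMT2D siRNAs, 66 raised and 68 lowered genes were called for no KMT2C siRNA in that direction. All 3 KMT2C siRNAs raised 51 genes and lowered 1, CYP4F3 (independent lists 0.0187 and 0.00475), with log2 fold changes of -1.79, -1.76 and -1.66. Of these, 3 were called for no KMT2D siRNA in that direction, CYP4F3, MAPK1IP1L (ENSG00000168175; 1.13, 0.93 and 1.16) and the linker histone gene H1-10 (ENSG00000184897; 1.18, 1.32 and 0.92), which were named after their values were seen. Sets of 3 siRNAs that mixed the targets shared 50 to 106 genes against the same control, beside 52 for the 3 KMT2C siRNAs. The lists of the siRNAs differ in length, so these counts do not rank the sets. Alone, KMT2D siRNA1 changed 845 genes, siRNA2 1875, KMT2C siRNA1 252, siRNA2 1222 and siRNA3 131, and 56.7%, 70.7%, 36.1%, 62% and 17.6% of these were called for no other siRNA. The counts of genes shared by all 5 siRNAs fell to 21 without the PANC1 control, 23 without PANC1 KMT2C siRNA3, 17 without the SUIT2 control and 24 without SUIT2 KMT2C siRNA3. Those shared by both KMT2D siRNAs fell to 159, 111 and 134 without PANC1 KMT2D siRNA1, the SUIT2 control or SUIT2 KMT2D siRNA1. Those shared by all 3 KMT2C siRNAs fell to 23, 29, 27, 32 and 32 without the PANC1 control, PANC1 KMT2C siRNA3, the SUIT2 control, SUIT2 KMT2C siRNA1 or SUIT2 KMT2C siRNA3. For KMT2D siRNA1 against control siRNA the count fell to 426, 371 and 312 (without its PANC1 library, the SUIT2 control or its SUIT2 library). For KMT2D siRNA2 against control siRNA it fell to 1173, 1149 and 1140 (without the PANC1 or SUIT2 control or its SUIT2 library). Left out in turn were the PANC1 control, the SUIT2 control, the PANC1 library and the SUIT2 library of each KMT2C siRNA. The count then fell to 99, 119, 93 and 59 for KMT2C siRNA1 against control siRNA, to 537, 740, 665 and 608 for KMT2C siRNA2 against control siRNA and to 64, 73, 65 and 50 for KMT2C siRNA3 against control siRNA.

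**Figure D3:**
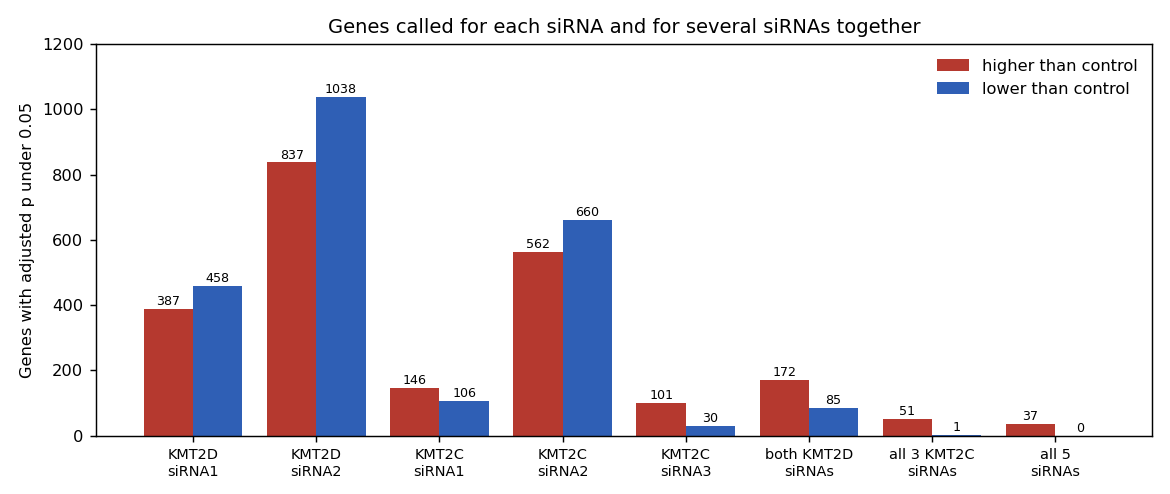
Number of genes with an adjusted p under 0.05 that were higher or lower than control for each siRNA alone and for every siRNA of a set together, as bars from 0. Both KMT2D siRNAs share 172 raised and 85 lowered genes, all 3 KMT2C siRNAs 51 and 1, and all 5 siRNAs 37 and 0.

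With each siRNA, genes that carried certain heptamers in the 3′ UTR were lower than other genes. The heptamer found in 2 lines lay within the lowest 0.001 of all heptamers in the line left out in 14 of 15 cases and ranked first in 12. The exception was KMT2C siRNA3 in COLO357, an siRNA for which the search without PANC1 gave another heptamer (TCAATCA) than the other searches. The control siRNA, counted apart, gave 3 of 3, but with a different heptamer each time (TGACGTA, GACAGTA and AGACGTA, at ranks 4, 13 and 4). Genes with GCTAGTA fell by 0.424 on the log2 scale with KMT2C siRNA2, those with GCATCAT by 0.311 with KMT2D siRNA1, and those with ACTGTCA by 0.256 with KMT2D siRNA2. Those with TGACGTA fell by 0.242 with the control siRNA, with AAACGGA by 0.194 with KMT2C siRNA1 and with GTCAATC by 0.117 with KMT2C siRNA3. In the library labelled PANC1 KMT2C siRNA2, genes with GCTAGTA, as found in the other 2 lines, fell by 0.461, the lowest of all heptamers. Of the searched genes lowered by 1 siRNA and called for no other, 133 of 270 carried its heptamer for KMT2D siRNA1 (49.3% against 9.17% of other genes), 109 of 382 for KMT2C siRNA2 (28.5% against 4.56%). The heptamer was carried by 16 of 57 for KMT2C siRNA1 (28.1% against 3.38%) and 12 of 15 for KMT2C siRNA3 (80% against 4.02%). These shares are raised by the choice of each heptamer on the same genes and libraries. For KMT2D siRNA2 the count is void, since only 79.5% of its genes had a searched 3′ UTR.

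**Figure D4:**
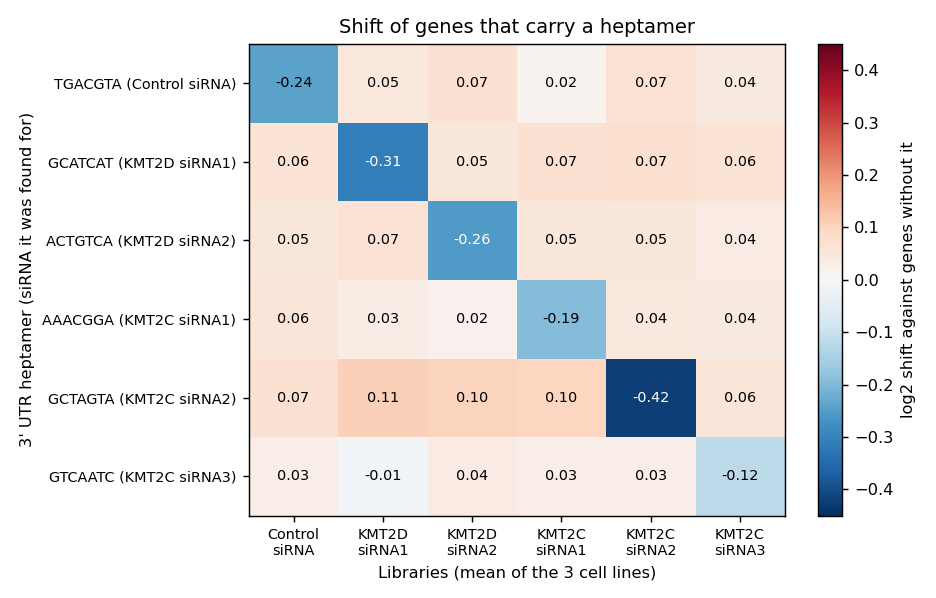
Log2 shift of genes that carry a 3′ UTR heptamer against genes without it, for the heptamer found for each siRNA (vertical axis) in the libraries of each siRNA (horizontal axis, mean of 3 cell lines). The diagonal heptamers were found on the same libraries and shift by -0.42 to -0.12, and the other values are largely fixed by them, since each library was set against the mean of the other 5 of its line.

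Among the genes called per target, the responses to KMT2C and KMT2D siRNA overlapped only in genes that rose. MET, MSRB3, PTPMT1, RBPJ and CALU were among 46 genes that were higher with both (0.391 for independent lists), 0 were lower with both (0.0151), and 0 moved in opposite directions. Only 3 genes were called lower with KMT2C siRNA, so the lack of shared falls tells little. Single siRNAs of different targets did share falls, from 6 genes for KMT2D siRNA1 and KMT2C siRNA3 (0.653 for independent lists) to 118 for KMT2D siRNA2 and KMT2C siRNA2 (32.6). Simulated unchanged groups with shared controls gave 0 genes called in both comparisons in each of 20 simulations. No siRNA effect was drawn in them, so a count of 0 was near certain. Across the 21028 genes, log2 fold changes of the 2 comparisons correlated with r = 0.559, below the 0.71 (0.702 to 0.718) that shared controls alone gave, and had the same sign in 65.9% of genes against 74.8%. Their covariance was 0.139 against 0.111 simulated (0.109 to 0.113), a difference of 0.0281. Genes are not independent replicates, each line has 1 control library that cannot be split, and part of the overlap may come from these shared controls.

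Within single lines few genes passed. In SUIT2, KMT2D siRNA raised RBPJ (2.18, SE 0.329), the mitochondrial import receptor TOMM20 (1.86, SE 0.291), CALU (1.77) and the prelamin A protease ZMPSTE24 (1.68, SE 0.267). It lowered PIK3CB (-1.98, SE 0.277), the transcription factor CREB3L3 (-4.42, SE 0.622), AMER1 (-2.28, SE 0.364) and the pseudogene HNRNPA1P33 (-2.45, SE 0.392), and KMT2C siRNA raised RBPJ (2.33, SE 0.323, adjusted p = 0.0311). By edgeR's quasi-likelihood test these 8 genes (4 higher, 4 lower) and 1 gene were called in SUIT2, and 0 in PANC1 and COLO357 for either target. Unadjusted p lay under 0.05 for 1290 (PANC1), 608 (COLO357) and 1651 (SUIT2) genes with KMT2D siRNA and for 893, 692 and 1124 with KMT2C siRNA. The 608, 692 and 893 are fewer than chance alone gives among 21028 genes, while 1124, 1290 and 1651 are more. DESeq2 called 105, 7 and 188 genes with KMT2D siRNA and 36, 7 and 86 with KMT2C siRNA. In COLO357, DESeq2 called PIK3CB (-1.71), KRT80 (-2.30), MCAM (-1.85), MBTPS1 (1.06), DNAJC6 (-1.64), CALU (1.16) and the pseudogene RPSAP12 (3.77) with KMT2D siRNA, and CYP4F3 (-2.19), DPP4 (-2.70), RHOB (1.60), CALU (1.28), PIP4K2A (1.18), RPSAP12 (3.59) and RPSAP47 (-0.91) with KMT2C siRNA. All these line-wise genes were named after their values were seen. The SUIT2 count for KMT2D was 30 without siRNA1 and 1 without siRNA2, that for KMT2C was 0 without siRNA3, and the PANC1 counts were 1 without KMT2D siRNA2 and 1 without the library labelled PANC1 KMT2C siRNA2.

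No gene differed between lines in its response by edgeR's interaction test (0 genes for each target). The design recovered 18.2% of simulated 4-fold differences. At an unadjusted p under 0.05 there were 475 genes for KMT2D and 469 for KMT2C, against 1182 and 1150 with each siRNA as a term. The 475 and 469 are fewer than chance alone gives among 21028 genes, so they are no sign of differences between lines. Why they are so few was not tested. The smallest p for KMT2D were those of ZMPSTE24 (log2 fold changes of -0.20 in PANC1, 0.19 in COLO357 and 1.68 in SUIT2), RPSAP12 (0.19, 3.77 and -0.33), the extracellular matrix protein SVEP1 (1.28, -1.42 and 6.65), GDPD5 (3.22, 0.53 and -0.96) and A4GALT (1.96, 0.10 and -0.90), all with an adjusted p of 1. For KMT2C they were RPSAP12 (-0.39, 3.58 and -1.68, adjusted p = 0.245), the adhesion molecule ICAM1 (0.60, 0.80 and -2.11), the telomerase RNA TERC (0.12, 0.71 and -0.85), ZMPSTE24 (-0.36, -0.15 and 1.10) and the myosin kinase MYLK (0.79, -1.33 and 0.49), the last 4 with an adjusted p of 1. The pseudogene RPSAP12 is uncertain because it can share reads with RPSA and its other copies. DESeq2's likelihood ratio test called 4 genes for KMT2D (ZMPSTE24, SVEP1, RPSAP12 and MIR205HG, the last with adjusted p = 0.0361) and 3 for KMT2C (RPSAP12, TERC and ZMPSTE24, the last with adjusted p = 0.0184).

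An siRNA changed expression in a way that was recognisable in another cell line, and more so than its target. Library log2 fold changes against the own line's control correlated across genes with a mean r = 0.201 between lines for the same siRNA (15 pairs, 0.0495 to 0.313). The mean was 0.079 for different siRNAs of the same target (24 pairs) and 0.0467 for siRNAs of different targets (36 pairs). All pairs are set against a control siRNA of the same label, whose own effects could raise each of these means. The excess of the same siRNA over other siRNAs was 0.141 (exact permutation p = 6.94e-05, the smallest that 14400 arrangements can give), and in 12 of 15 cases the best match was the same siRNA. The excess of the same target over the other target was 0.0324 (exact permutation p = 0.1, the smallest that 10 arrangements can give), so this test could not pass 0.05. By siRNA the mean was 0.282 for KMT2D siRNA2, 0.242 for KMT2C siRNA2, 0.241 for KMT2D siRNA1, 0.124 for KMT2C siRNA3 and 0.117 for KMT2C siRNA1. Among the searched genes alone, the same siRNA correlated more than other siRNAs in 7218 genes with none of the 6 heptamers (0.328 against 0.101, an excess of 0.226) and in 3161 genes with at least 1 (0.478 against 0.15, an excess of 0.329). Genes with none of these 6 may hold other sites of the siRNAs. The correlations run over genes, which are not independent replicates.

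**Figure D5:**
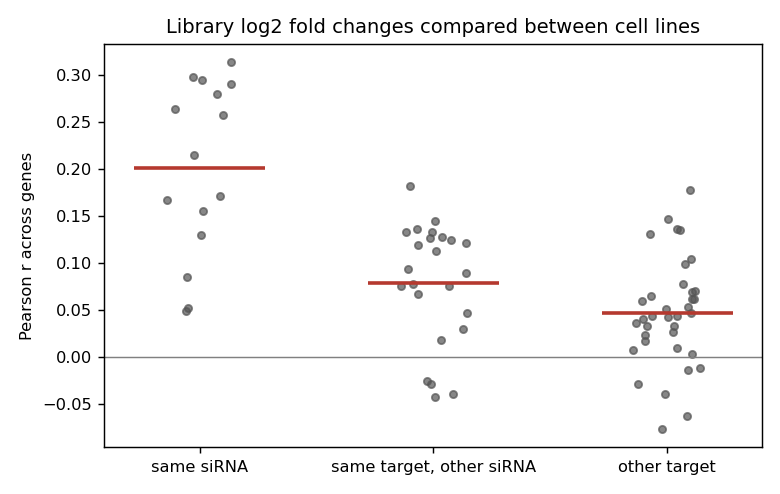
Pearson correlation across genes of library log2 fold changes for pairs of libraries from different cell lines, for the same siRNA, another siRNA of the same target and the other target. Dots are pairs and red lines are means (0.201, 0.079 and 0.0467).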

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

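Of the tests here, those with 5 control heptamers, the fits with the share of read pairs in no annotated feature as a covariate and the fits without the 3 libraries above 20% were chosen after the results had been seen.

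Among 59 groups of libraries examined for a library far from the rest, 4 held one, where chance gives about 5% of groups. ADAM32 rose by 2.98 on the log2 scale in SUIT2 KMT2D siRNA2, against 1.27 to 1.9 in the other KMT2D libraries, a gap of 0.631 of the whole range. PTPMT1 rose by 2.97 in SUIT2 KMT2C siRNA1, against 0.873 to 1.91 in the other KMT2C libraries, a gap of 0.504 of the range. SCEL stood at -3.13 in SUIT2 KMT2C siRNA1, against -0.901 to 0.102 in the other KMT2C libraries, a gap of 0.69 of the range. CP stood at 1.19 in PANC1 KMT2D siRNA2, against -0.105 to 0.362 in the other KMT2D libraries, a gap of 0.639 of the range. The share of read pairs in no annotated feature, which lies outside the gene counts, averaged 17.2% with KMT2C siRNA and 12.8% with control siRNA, and lay above the own line's control in 6 of 9 KMT2C libraries and 2 of 6 KMT2D libraries.

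PTPMT1, MET, SLC36A1, WSB1, RBPJ and CALU were among 37 genes that rose with all 5 siRNAs against the control siRNA. Simulations of unchanged groups with shared controls gave at most 0 such genes. They drew no siRNA effect and called a mean of 0.05 raised genes for each target, so a count of 0 was near certain. Chance values of the 3 control libraries beside real changes were thus not excluded. With the share in no annotated feature as a covariate the median log2 fold change was 1.15 (quartiles 0.94 to 1.39), as it was without (1.15, quartiles 0.934 to 1.35), with 28 of the 37 keeping all 5 calls, and without the 3 libraries above 20% it was again 1.15 (quartiles 0.941 to 1.37) while 1 gene kept all 5 calls, because KMT2C siRNA3, left with 1 library, called 1 of the 37 at a median standard error of 0.253 in place of 0.175 and the 4 other siRNAs had 29 called by each, so that the size argues against that share as the whole cause while the calls were not kept. A candidate explanation is seed-matched repression by the control siRNA itself, since of 34 searched genes 24 carried 1 or more of the control heptamers TGACGTA, GACAGTA, AGACGTA, GACGTAT and GACGTAA, which were found without these genes (70.6% against 12.7% of other genes; one-sided Fisher exact p = 1.33e-14; length-matched lists averaged 5.04, permutation p = 0.0001, the smallest that 10000 lists can give), while CALU, PDCD6, BANF1, PPP2R1B, GAS2L1 and PTPN1 carried none. The count of TGACGTA alone (3 of 34, RBPJ and PTPN14 among them, 8.8% against 1.74%; one-sided Fisher exact p = 0.0216) adds little, because that heptamer was found with these genes, which are low in the controls by definition, included. A response shared by both targets stays open as untested, because each line had 1 control siRNA.

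KMT2D siRNA2 lowered 820 genes and KMT2C siRNA2 473 that were called for no other siRNA. Seed-matched repression by each siRNA is a candidate explanation: the heptamer found for an siRNA in 2 lines lay within the lowest 0.001 of heptamers in the line left out in 14 of 15 cases. For KMT2D siRNA1, KMT2C siRNA1, siRNA2 and siRNA3, 49.3%, 28.1%, 28.5% and 80% of the searched genes carried the own heptamer, shares raised by its choice on the same genes. Most searched genes of KMT2D siRNA1 and of KMT2C siRNA1 and siRNA2 did not carry that 1 heptamer. Others tied to lower levels, such as CATCATA (-0.183 with KMT2D siRNA1) and TGCTAGT (-0.254 with KMT2C siRNA2), were not counted. These shares thus cannot tell how many genes hold any seed match. The same count is void for KMT2D siRNA2, since only 79.5% of its genes had a searched 3′ UTR. A different degree of target loss with each siRNA stays open as untested.

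KMT2C and KMT2D siRNA differed in 1087 genes, among them MDC1, PIK3CB, SCEL and ALDH1A1, and by 6.05 percentage points in the share of read pairs in no annotated feature. The slope on that share within groups accounted for a median of 0.0288 of the log2 fold change of these genes (0.023 to 0.0442 when each library was left out), which argues against it as the cause of most of the difference in the typical gene. Genes with values of opposite sign offset each other in that median, so single genes may differ. Within a group each library has another siRNA, so the slope cannot be parted from the siRNAs. With the share as a covariate all 1087 genes kept their direction and the median size went from 0.679 to 0.655, but the median standard error rose from 0.16 to 0.189 and 152 of them were called again, so that calls ended with a wider error beside little change in size. Without the 3 libraries above 20%, which leaves KMT2C siRNA3 with 1 library, 342 genes were called. A difference between the targets themselves, and off-target effects of the siRNAs, stay open, since no test here parts them.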

How the results depend on the processing

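The fits without the 3 libraries above 20% in no annotated feature, with that share as a covariate, with each siRNA as a term and with numbers 1 and 2 but no block were chosen after the data had been seen. So were the DESeq2 size factors for lists, and the fits without single libraries for the single and shared siRNA counts and for named genes.

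The 20 genes named for KMT2D siRNA, the 13 for KMT2C siRNA and the 10 for their comparison kept their direction with DESeq2, with an siRNA block and without each siRNA or library, and all were called by DESeq2. With each siRNA as a random block (voom correlation 0.211) 10, 9 and 9 were still called, without the SUIT2 control 2 of 20 and 4 of 13. The cause of changes in the counts below was not tested, except that fits with fewer libraries have less power where counts fell and that, on counts simulated for the KMT2D comparison, 14.4% of DESeq2's calls were false against 3.37% of edgeR's. Those simulations drew no effect shared by the libraries of an siRNA, so the false shares may differ in the real counts. Depth limits genes at a few counts per library.

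KMT2D siRNA against control called 253 genes, but 660 by DESeq2, 657 without a filter on low counts, 53 with the compared libraries alone and 77 with the siRNA block. It called 1142 without siRNA1, 504 without siRNA2, 46, 88 and 30 without PANC1, COLO357 or SUIT2, and 36 to 320 without single libraries. KMT2C siRNA against control called 59 genes, but 217 by DESeq2, 270 without a filter, 26 with the siRNA block, 3, 9 and 6 without PANC1, COLO357 or SUIT2, 37 without the 3 libraries, and 7 to 74 without single libraries. KMT2C against KMT2D siRNA called 1087 genes, but 1939 by DESeq2, 1762 without a filter, and 288 with the siRNA block. It called 1839 and 1651 without KMT2D siRNA1 or siRNA2, 587 and 369 without KMT2C siRNA1 or siRNA3, and 96, 283 and 109 without PANC1, COLO357 or SUIT2. It called 342 without the 3 libraries, 153 with the covariate, and 672 to 1225 without single libraries. The siRNA numbers do not pair the samples: deviations of libraries with the same number correlated with r = -0.0065, 0.11 and -0.0111 in PANC1, COLO357 and SUIT2. With the number as a replicate block on numbers 1 and 2 the comparison called 649 genes, and 167 on the same libraries without the block.

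The genes changed by both KMT2D siRNAs numbered 257, but 423 by DESeq2, 95 without PANC1, 66 without SUIT2 and 111 to 292 without single libraries. The genes changed by all 3 KMT2C siRNAs numbered 52, but 107 by DESeq2, 5 and 22 without PANC1 or SUIT2, 1 without the 3 libraries and 23 to 69 without single libraries. The genes changed by all 5 siRNAs numbered 37, but 70 by DESeq2, 4 and 12 without PANC1 or SUIT2, 1 without the 3 libraries and 17 to 43 without single libraries. KMT2D siRNA1 against control siRNA called 845 genes, but 1290 by DESeq2 and 312 to 1038 without single libraries. KMT2D siRNA2 against control siRNA called 1875, and 1140 to 2120 without single libraries. KMT2C siRNA1 against control siRNA called 252, but 496 by DESeq2 and 59 to 365 without single libraries. KMT2C siRNA2 against control siRNA called 1222, but 1866 by DESeq2, 533 without the 3 libraries and 537 to 1530 without single libraries. KMT2C siRNA3 against control siRNA called 131, but 344 by DESeq2, 4 without the 3 libraries and 50 to 184 without single libraries.

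Within PANC1, COLO357 and SUIT2, edgeR called 0, 0 and 8 genes with KMT2D siRNA (0 to 1, 0 and 1 to 30 without single libraries) and 0, 0 and 1 with KMT2C siRNA (0 to 1, 0 and 0 to 1). DESeq2 called 105, 7 and 188 with KMT2D siRNA and 36, 7 and 86 with KMT2C siRNA. The difference between lines called 0 and 0 genes, 4 and 3 by DESeq2's likelihood ratio test, and for KMT2C 1 gene, RPSAP12, with each siRNA as a term. The lipid synthesis list reversed without KMT2D siRNA2, to an adjusted p of 0.649 against control and 0.00146 between the targets. All 22 lists had the same call with DESeq2's size factors in each comparison. The correlation of the same siRNA between lines stayed above that of other siRNAs with Spearman's coefficient, at 10 CPM and without KMT2C and KMT2D (excess of 0.151, 0.277 and 0.141; exact permutation p = 6.94e-05 in each).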

Other observations

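The counts and genes in the first paragraph and the correlation in the second were chosen after the results had been seen; the splits of single libraries in the last were planned, and those of whole siRNAs were chosen after the results had been seen.

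EXO1, an exonuclease of mismatch repair, fell by 1.32 and 0.98 on the log2 scale with KMT2D siRNA1 and siRNA2, the replicative polymerase gene POLE by 0.74 and 0.64, the cell cycle phosphatase gene CDC25B by 0.73 and 0.77 and the kinetochore gene MIS12 by 0.81 and 0.63. The receptor kinase MERTK fell by 0.82 and 1.04, the retinoic acid receptor RARG by 1.11 and 0.91, the 14-3-3 protein gene SFN by 0.75 and 0.90 and the RNA-binding protein gene LIN28B by 2.36 and 2.74. The histone genes H1-4 (-0.83 and -0.86) and H2AC6 (-0.63 and -0.60) were lower as well but are uncertain, since histone genes share sequence. They were chosen from 68 genes lowered by both KMT2D siRNAs and called lower for no KMT2C siRNA, as members of the 60 that were also called higher with KMT2C than with KMT2D siRNA. That contrast uses the same libraries, so it is part of the choice and no separate evidence. Of these 60, 48 had a searched 3′ UTR and 27 carried a heptamer found for a KMT2D siRNA, which the genes named here did not. Only 1 heptamer was counted for each KMT2D siRNA, so the named genes may hold other sites. Of 66 genes raised by both KMT2D siRNAs and called higher for no KMT2C siRNA, 32 were called lower with KMT2C than with KMT2D siRNA. Chosen from these, among genes whose searched 3′ UTR held no control heptamer, were the annexin ANXA1 (0.88 and 1.95), GPR137B (1.57 and 1.07) and the integrin subunit ITGB8 (0.85 and 1.38), which did carry a KMT2D siRNA heptamer. The iron-sulfur cluster scaffold ISCU (0.64 and 0.61) and the ornithine aminotransferase OAT (0.60 and 0.61) were chosen likewise.

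The share of gene counts taken by ENSG00000226958, to which no name was matched, ran from 0.073% to 2.487% of gene counts and followed the share of read pairs in no annotated feature over the 18 libraries (Pearson r = 0.882, Spearman rho = 0.827, permutation p = 6e-05 for each, 2-sided). Without the 2 libraries farthest from the median r was 0.63, and within the lines it was 0.978 in PANC1, 0.985 in COLO357 and 0.942 in SUIT2.

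Single libraries were regrouped within their cell lines to see how often other groupings call as many genes. Splits that mixed reagents between lines broke up each siRNA. Against control, they called at most 1 gene for KMT2D and at most 2 for KMT2C. A small share of splits can thus exclude only a chance mixing of libraries and says nothing of the target. For KMT2D siRNA against control, 3 of the 27 splits gave at least the real 253 genes, so the splits alone could not exclude chance. The 2 others made one KMT2D siRNA the control in all 3 lines. The highest, with KMT2D siRNA2 as the control, called 1349 genes, several times the real count, which points to a structure of the samples by siRNA. For KMT2C siRNA against control, 2 of 64 splits gave as many as 59, so only a chance mixing of single libraries was excluded. The other one, with KMT2C siRNA2 as the control, called 625 genes, a sign of the same structure, and the 4 splits with one reagent as the control in all 3 lines are too few for a share under 0.05. For KMT2C against KMT2D siRNA (1087 genes; highest other split 44), genes changed by both KMT2D siRNAs (257; 14), by all 3 KMT2C siRNAs (52; 12) and by all 5 siRNAs (37; 7), chance was excluded for single libraries only, with 1 of 100 splits, the real one, as large. When the 3 libraries of each siRNA were kept together, KMT2C against KMT2D siRNA had 10 splits, too few for a share under 0.05 (1087 genes; highest other 358). Of 60 such splits, 35 gave as many genes as the 257 changed by both KMT2D siRNAs (highest other 1045) and 43 as many as the 52 changed by all 3 KMT2C siRNAs (highest other 736), so a chance choice of siRNAs could not be excluded for either. The 6 choices of the control siRNA are too few for a share under 0.05 for genes changed by all 5 siRNAs (37; highest other 394, with KMT2D siRNA2 as the control). The 4 splits of a single siRNA against control are too few for a share under 0.05. The real one (1 of 4) called 845, 1875, 252, 1222 and 131 genes for KMT2D siRNA1 and siRNA2 and KMT2C siRNA1, siRNA2 and siRNA3, and the highest other 1, 0, 4, 0 and 0.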
